A study of Danio rerio with 71 samples.

How the data were processed

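Pools of 10 to 12 neurons were collected by pipette from Tg(tph2:GFP) zebrafish at 7 days post fertilization and sequenced as 3' end libraries, giving 71 libraries in 7 groups of 9 to 12. The authors deposited 1 table of counts per gene and library, and all values here start from these deposited counts. The aligner, the counting program, the annotation and any use of molecular identifiers are not given in the sources used here. Genome build danRer11, R 4.3.1 and Seurat 5.0.2 are named in the labels without a role. The table has 20635 rows, of which 68 have no gene name and 674 share a name with another row, and 19526 of its identifiers are in the reference table of gene names, which was used for names only. A genome sequence was not used here, and no coordinates are given.

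Groups were taken from the sample titles. The protocol uses a second set of names for 5 of the groups (those from SR-R to IR-C), which the labels do not match to the titles. Title names are used throughout. The labels give no batch, date or fish. A rule on depth, set before the data were examined, left out 0 libraries. A gene counted as detected with 1 count. A group in which all libraries were at 0 got an upper limit of 3 counts over the group, which is 0.169 CPM in PT, 0.129 in R_DRN, 0.145 in M_DRN, 0.159 in C_DRN, 0.0743 in IN_A, 0.137 in IN_P and 0.106 in MO (over IN_A and IN_P together, 0.0482). These limits and 95% counting intervals cover counting error only, not the spread between pools.

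Differences were tested in R 4.3.3 with edgeR 4.0.16, in 1 model of all 71 libraries with 7 group coefficients (filterByExpr by group with a minimum count of 10, TMM factors, estimateDisp, robust glmQLFit, quasi-likelihood F-test). It tested 10093 genes with 64 residual degrees of freedom and a common dispersion of 4.82, and adjusted p-values by the Benjamini-Hochberg method with a threshold of 0.05. The 13 comparisons were any difference, each group against the mean of the other 6 coefficients, the 3 DRN against the 2 IN groups, the 3 pairs of DRN groups, and IN_A against IN_P. Means and SDs of single genes are in TMM-scaled counts scaled to a common total (CPM), and those of lists in CPM of the library total.

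Gene lists, 29 in number, were fixed by name or naming pattern before the data were examined. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, and as an alternative an estimated correlation), adjusted over lists within a comparison. Members past the threshold were counted with adjustment over all genes and over the list alone. The level of each list, log2 of summed CPM plus 1, was compared across groups by permuting the F statistic 100000 times, adjusted over lists. The same permutation test was used for the number of genes detected, for totals on the log2 scale, and for libraries thinned to 1138419 counts, the smallest total. The nearest library was the one with the highest Spearman correlation of log2 CPM plus 1 over the 2000 most variable genes.

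Genes were named by a rule fixed before the data were examined. For each group against the other 6, genes had to pass the threshold, be counted in at least 75% of the libraries on the higher side and have medians in the direction of the fitted change; the 10 largest increases, the 5 largest decreases and up to 10 members of the lists by smallest adjusted p were then named. The DRN and IN comparison used 10, 10 and 10, each pair of groups 5, 5 and up to 10, and the test of any difference the 10 smallest p-values. Genes known only by a clone or accession and mitochondrial transcripts were not ranked. The genes tph2, slc6a4a, slc18a2, fev, slc17a6b, slc17a8, gad2, gad1b, slc32a1, tph1a and ddc were always followed. Other genes in the report were chosen after their values were seen.

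Alternatives chosen before the data were examined were DESeq2 1.42.0, its size factors in place of TMM factors, no filter on low counts, the number of genes detected as a covariate, only the compared groups, a replicate block from the numbers in the titles, list levels with a pseudocount of 10 or TMM scaling, and 500 genes or a Pearson correlation for the nearest library. Added later were limma (trend, robust) on log2 CPM, the test of each group against each other group, and the fit without IN_A 7 and IN_P 6. Every count of genes or lists was set against 99 random regroupings of the same libraries. The pipeline was tested on simulated data with known changes, where a large share of the calls by edgeR and DESeq2 in comparisons of 1 group with the other 6 were genes that had not been changed, and few with limma. For this reason counts by edgeR are given beside those shared with limma. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.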

Results

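Neurons that carried a tph2 reporter, a label of cells that make the serotonin-synthesizing enzyme of the brain, were picked with a glass pipette from the brains of zebrafish at 7 days post fertilization. Each of 71 libraries held the 3' ends of messenger RNA from a pool of 10 to 12 such neurons. The sample titles placed them in 7 groups named PT (10 libraries), R_DRN (9), M_DRN (10), C_DRN (9), IN_A (12), IN_P (10) and MO (11). Nothing in the labels says that the pools came from different fish, so every p-value below measures only the spread between pools, and the labels give no batch or date. The deposited table held 20635 gene rows. Total counts ranged from 1.14 to 5.47 M per library (median 2.15 M). Their means were 1.77 ± 0.791 M in PT, 2.59 ± 0.790 in R_DRN, 2.07 ± 0.590 in M_DRN, 2.09 ± 0.585 in C_DRN, 3.36 ± 1.17 in IN_A, 2.19 ± 0.933 in IN_P and 2.58 ± 0.610 in MO (SD). Totals differed between the groups (permutation p = 0.00025). Between 5713 and 9863 genes were detected per library (median 7353). The groups did not differ detectably in that number (permutation p = 0.414), nor when every library was thinned to 1138419 counts (permutation p = 0.0535).

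All 7 groups held the transcripts of serotonin synthesis, but at unequal levels, and MO stood apart in the genes that store and recover the transmitter. The mean level of tph2, the serotonin-synthesizing enzyme, lay between 2499 and 5946 counts scaled to a common library total (CPM) in 6 groups and at 684 ± 489 CPM in MO (SD, n = 11). The serotonin transporter gene slc6a4a averaged 427 to 1788 CPM in those 6 groups and 9.71 ± 21.2 in MO, where 4 of 11 libraries had any count. The vesicular amine transporter gene slc18a2 averaged 272 to 434 CPM in the 6 groups and 6.34 ± 20.3 in MO. A paralog of the membrane transporter gene, slc6a4b, showed the reverse, with 105 ± 90.7 CPM in MO and at most 0.106 in any other group. The transcription factor gene fev, part of the program of hindbrain serotonin neurons, averaged 830.3 to 1238 CPM in the DRN and IN groups, 0.317 ± 0.442 in PT and 0.416 ± 1.06 in MO. The mean of slc6a4a in MO was 5 CPM without MO 8 and that of slc18a2 in MO was 0.223 CPM without MO 8.

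**Figure D1:**
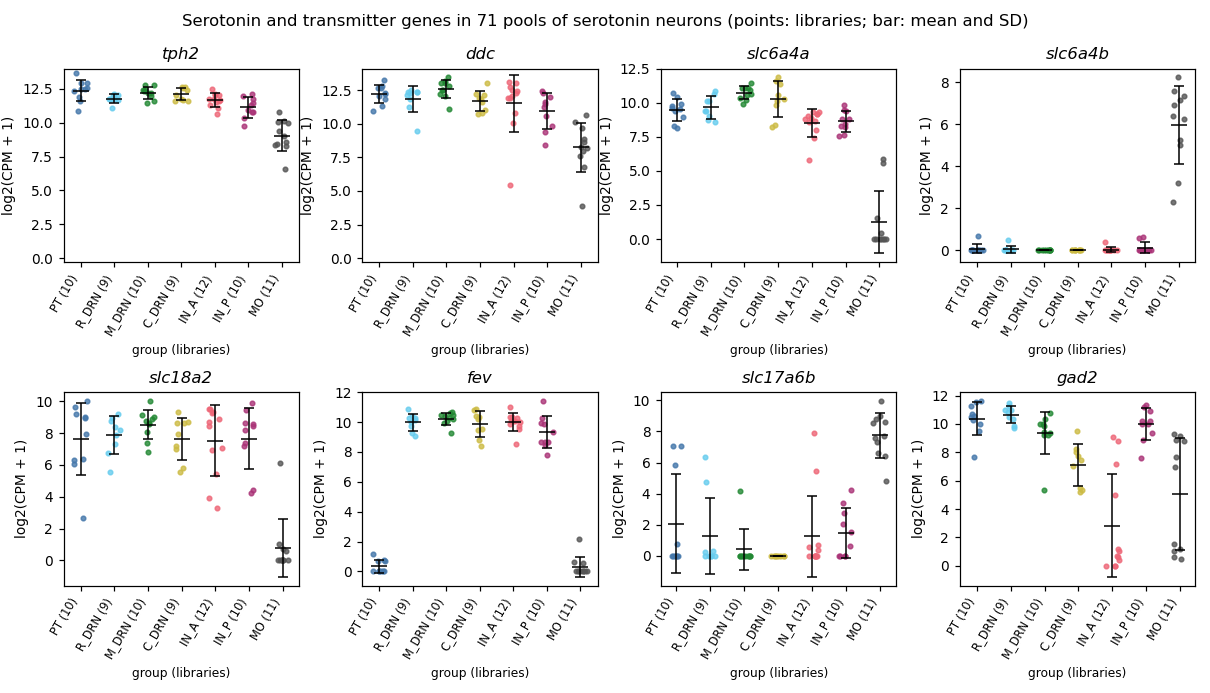
Levels of 8 genes of serotonin, glutamate and GABA transmission in the 71 libraries, as log2 of CPM plus 1 on the vertical axis and the 7 groups, with their number of libraries, on the horizontal axis. Points are libraries and bars are the mean and SD, and slc6a4a averaged 9.71 CPM in MO against 427 or more in the other groups.

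Markers of other transmitters also separated the groups. The GABA-synthesizing enzyme gene gad2 averaged 1638 ± 957 CPM in PT, 1737 ± 678 in R_DRN, 857 ± 456 in M_DRN and 1252 ± 777 in IN_P, and lower values in C_DRN (213 ± 210.4), MO (221 ± 254) and IN_A (97.4 ± 192). The summed level of the GABA and glycine list ran from 5443 ± 1711 CPM in R_DRN to 1037 ± 715 in IN_A (adjusted permutation p = 2.42e-05). Of the vesicular glutamate transporters, slc17a6b averaged 315 ± 278 CPM in MO and at most 32.2 elsewhere, while slc17a8 averaged 167 ± 85.8 in M_DRN, 148 ± 137 in C_DRN and 175 ± 235 in IN_P and had no count in MO. The glutamate list differed between the groups at an adjusted permutation p of 0.000612. Genes of other amines and of acetylcholine did not (adjusted permutation p = 0.16), and tph1a, a second tryptophan hydroxylase gene, had counts in 6 of 71 libraries. The mean of gad2 in IN_A was 56.1 CPM without IN_A 56 and that of slc17a6b in PT was 20.8 CPM without PT 12.

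Whole profiles followed the group names. For 58 of the 71 libraries (81.7%), the library with the most similar profile belonged to the same group (13.2% on average with permuted names, one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The permutation did not keep libraries with neighbouring title numbers together, and in PT, IN_A and MO many nearest libraries carried neighbouring numbers. All libraries of PT, M_DRN and MO had a nearest neighbour of their own group, as had 11 of 12 IN_A and 9 of 10 IN_P libraries. Within the DRN the borders were weaker: 3 of 9 R_DRN and 4 of 9 C_DRN libraries were nearest to their own group, the others being nearest to M_DRN. All 28 DRN libraries were nearest to a DRN library. The 10 M_DRN libraries and 9 of the 11 R_DRN and C_DRN libraries nearest to M_DRN were all nearest to 1 of the 5 M_DRN libraries with the most genes detected.

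A difference between any of the 7 groups passed the edgeR test for 2521 of 10093 genes tested, and limma called 1848. The 10 smallest adjusted p-values belonged to fev, pyya, shox2, hoxb3a, alpl, phox2bb, tlx3b, UBB, lmx1bb and met, of which fev, shox2, hoxb3a, phox2bb, tlx3b and lmx1bb encode transcription factors. Random regroupings of the libraries gave a median of 620 edgeR calls and at most 848, and at most 6 with limma. Counts by both tools are therefore given for each comparison, and named genes that edgeR called and limma did not are pointed out. Each group was compared with the mean of the other 6 to ask which genes set its transcriptome apart.

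**Figure D2:**
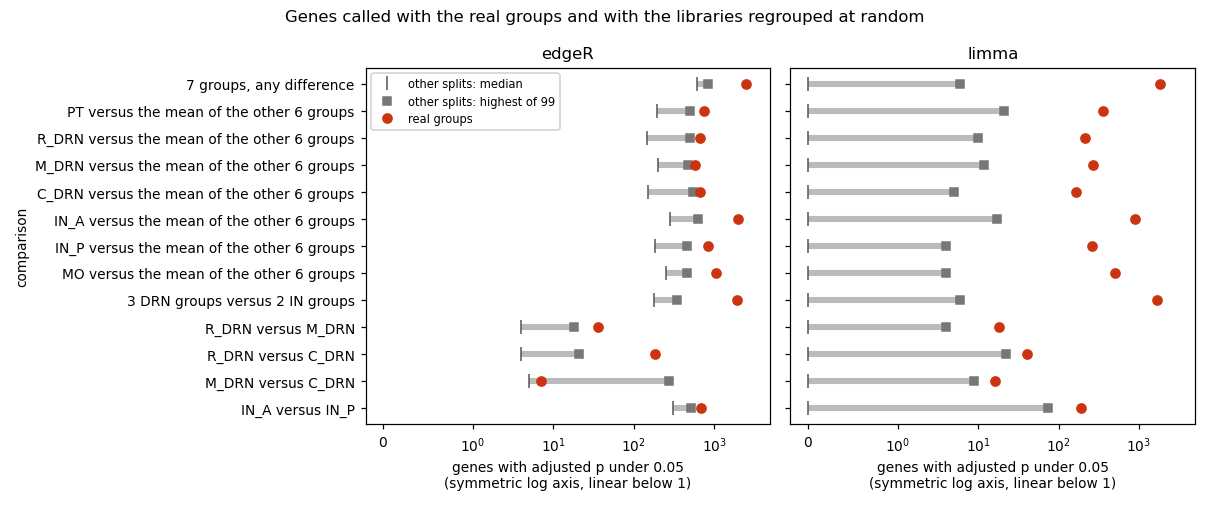
Number of genes with an adjusted p under 0.05 (horizontal axis, symmetric log scale) for each comparison (vertical axis) with edgeR on the left and limma on the right. Circles are the real groups, ticks and squares are the median and the highest of 99 random regroupings of the libraries, and the real count of M_DRN versus C_DRN by edgeR (7) lay within the regrouped counts, whose highest was 279.

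Summed levels of the fixed gene lists per library differed between the groups for 23 of 29 lists. Hox genes, which pattern the hindbrain along its length, averaged 2366 ± 667 CPM in MO, 2186 ± 1078 in IN_P and 781 ± 408 in IN_A, and 4.31 to 113 in the DRN groups and PT. Midbrain and isthmus genes were highest in M_DRN (8098 ± 2560.0) and R_DRN (7942 ± 1938) and lowest in PT (62.7 ± 96), and forebrain and pretectum genes were highest in PT (5454 ± 1979) with 210.5 to 1190.0 elsewhere. Neuropeptide precursors reached 28450 ± 7185 CPM in C_DRN and 8436 ± 3008 in M_DRN, against 623 in PT. Each of these lists, and those of serotonin identity, serotonin receptors, axon guidance, ribosomal proteins, the mitochondrial genome, radial glia and cerebellar neurons, reached an adjusted permutation p of 2.42e-05. The mean of the Hox genes list in R_DRN was 0.458 CPM without R_DRN 15 and that of the Hox genes list in C_DRN was 69.6 CPM without C_DRN 4.

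**Figure D3:**
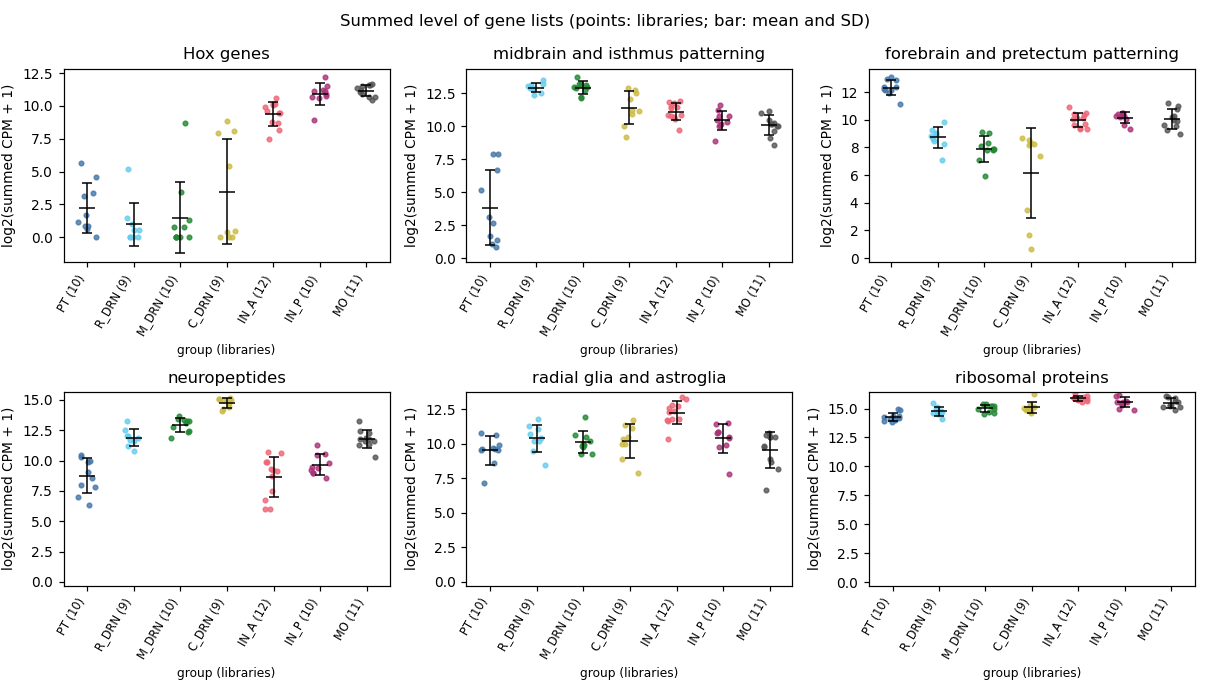
Summed level of 6 gene lists per library, as log2 of summed CPM plus 1 on the vertical axis and the 7 groups, with their number of libraries, on the horizontal axis. Points are libraries and bars are the mean and SD, and the Hox list averaged 2366 CPM in MO and 4.31 in R_DRN.

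Genes of excitability, adhesion and activity also differed between the groups. MO had the highest summed level of potassium channels (2579 ± 823 CPM, adjusted permutation p = 0.000794), of GABA-A and glycine receptors (2439 ± 479.5, p = 0.0031) and of ionotropic glutamate receptors (3926 ± 1182, p = 8.92e-05), the last against 1436 to 2396 elsewhere. Sodium, calcium and HCN channel genes did not differ detectably (adjusted permutation p = 0.0772), with means of 3029 to 4438 CPM. Receptors for adrenaline, dopamine, acetylcholine, histamine and orexin were highest in R_DRN (1203 ± 636) and lowest in IN_A (488 ± 272, p = 0.0125). With TMM-scaled CPM this list did not differ detectably (adjusted permutation p = 0.458). The levels here are in CPM of the library total, and the order of the groups can change with TMM scaling. Axon guidance genes were highest in IN_A (7792 ± 1647) and lowest in R_DRN (3760.0 ± 842), and cadherins and contactins highest in PT (8262 ± 1158) and lowest in IN_A (5278 ± 1879, p = 0.000526). Immediate early and stress genes, which activity and handling induce, averaged 6063 ± 4630.0 CPM in MO and 995 ± 614 in IN_A (p = 0.000529). Ribosomal protein genes ran from 20540 ± 5528 CPM in PT to 60340 ± 8984 in IN_A, and transcripts of the mitochondrial genome from 15780 ± 5072 in M_DRN to 35300 ± 6831 in IN_P.

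Markers of other cells differed as well. Radial glia markers averaged 5528 ± 2801 CPM in IN_A, oligodendrocyte and Schwann cell markers 3109 ± 5042 in IN_P (adjusted permutation p = 0.000124), cerebellar neuron markers 3285 ± 1444 in MO, muscle markers 493 ± 1119 in IN_P and 468 ± 637 in MO (p = 0.00938), proliferating progenitor markers 769 ± 1130.0 in IN_A (p = 0.000329) and skin markers 130.3 ± 240.3 in MO (p = 0.0223). Markers of microglia (adjusted permutation p = 0.0671), red blood cells (0.728), endothelium (0.0717) and photoreceptors (0.414) did not differ detectably, at means of at most 857, 99.6, 75.1 and 30.1 CPM. Skin markers did not pass with a pseudocount of 10 (adjusted permutation p = 0.0583), and microglia markers passed with TMM-scaled CPM (0.0424). The mean of the oligodendrocytes and Schwann cells list in IN_P was 1666 CPM without IN_P 9, that of the muscle list in IN_P was 149 CPM without IN_P 11 and that of the muscle list in MO was 291 CPM without MO 9. Medians of the oligodendrocytes and Schwann cells list were 839.5 CPM in IN_P and 879 in IN_A. The mean of the proliferating progenitors list in IN_A was 512 CPM without IN_A 7, that of the skin and epithelium list in MO was 74.7 CPM without MO 2 and that of the microglia and macrophages list in IN_P was 388 CPM without IN_P 6. The mean of the red blood cells list in MO was 16.9 CPM without MO 9, that of the endothelium and mural cells list in IN_P was 35 CPM without IN_P 40 and that of the retina and pineal photoreceptors list in PT was 0.701 CPM without PT 20.

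PT was set apart from the mean of the other 6 groups by genes of the forebrain and pretectum. The Wnt effector gene tcf7l2 averaged 3762 ± 1012 CPM in PT (SD, n = 10) and at most 37 elsewhere, and the homeobox genes emx2 (324 ± 240.3) and otx1 (230.1 ± 200.5) stayed at or below 14.7 in every other group. Of the forebrain and pretectum list, 8 of 14 tested members were higher and 0 lower (9 higher and 3 lower adjusted over the list alone), and the list was higher than other genes by limma camera (adjusted p = 5.49e-15). The orphan nuclear receptor genes nr4a2a (384 ± 378) and nr4a2b (313 ± 135), the alkaline phosphatase gene alpl (828 ± 513) and the enkephalin precursor gene penkb (155 ± 191) were also higher, with MO the next group, which for penkb (22.2) rested on MO 11. Of 8 serotonin receptor genes tested, 6 were higher, among them htr1aa, htr1b and htr5ab (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00038); htr1b did not pass limma. Cerebellar neuron markers were higher too (2 of 6 called; camera adjusted p = 0.0188), at 849 ± 486 CPM summed, above the DRN and IN groups (210.2 to 479.7) and below MO (3285). The mean of tcf7l2 in R_DRN was 2.6 CPM without R_DRN 8, that of otx1 in R_DRN was 1.56 CPM without R_DRN 8 and that of penkb in MO was 0.172 CPM without MO 11.

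The transcription factor genes lmx1al, lmx1bb and fev were nearly absent from PT, while most serotonin identity genes were not called. The LIM-homeobox gene lmx1al had no count in any PT library and averaged 35.4 to 407 CPM in the other groups, at least 1469.5-fold lower in PT than the mean over the other libraries. Its relative lmx1bb averaged 0.713 ± 1.14 CPM in PT and 568 to 1329 elsewhere. The midbrain and isthmus list was lower as a whole (camera adjusted p = 3.09e-13), with 2 of 10 members higher (zic2a and pax5) and 2 lower (2 higher and 2 lower adjusted over the list alone); pax5 was counted in PT 4 alone, with a group mean of 4.34 CPM and 0 without it, against 139 in R_DRN. The ribosomal protein list was lower (camera adjusted p = 3.42e-30; 26 of 87 members lower), as were Hox genes (8.05e-06) and neuropeptides (0.0188). Radial glia and oligodendrocyte markers were lower with the preset correlation of camera alone (adjusted p = 0.0188 and 0.00117, and 0.169 and 0.115 with an estimated correlation). The serotonin identity list, with 2 of 18 members higher (tph2 and gata3), 3 lower (fev, lmx1bb and nkx2.2a) and 13 not passing, had a camera adjusted p of 0.0403, and an adjusted p of 0.136 with an estimated correlation. Of these genes zic2a, pax5 and nkx2.2a did not pass limma. In all, edgeR called 745 genes (504 higher and 241 lower), limma 358, and 252 passed both in the same direction. More genes were lower by DESeq2 (324 higher and 523 lower). By limma, 36 genes were higher in PT than in each other group, a set chosen after the values were seen, among them tcf7l2, emx2, otx1, pknox2 (212 ± 220.4) and adarb1a (1179 ± 861). The mean of lmx1al in MO was 21.5 CPM without MO 12.

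R_DRN carried the highest means of en2a, en2b and pax5, 2 engrailed genes and a Pax gene of the midbrain-hindbrain boundary. Its libraries averaged 602 ± 625 CPM of en2b, 71.7 ± 66.2 of en2a and 139 ± 114 of pax5 (SD, n = 9), with M_DRN next at 208 ± 349, 12.8 ± 33.1 and 9.67 ± 28.2. Of 10 midbrain and isthmus members tested, 6 were higher and 1 was lower (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000102). The nicotinic acetylcholine receptor gene chrna2a, at 80.2 ± 84.8 CPM and counted in all 9 libraries, stayed at or below 2.13 elsewhere, and ucn3l, a precursor of a urocortin peptide, averaged 274 ± 202 CPM with M_DRN next at 76.5 ± 104. The list of adrenergic, dopamine, acetylcholine and orexin receptors was higher, with 3 of 12 members (chrna2a, adra1aa and hrh3) above the threshold (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00572), of which hrh3 did not pass limma. The mean of en2b in M_DRN was 101 CPM without M_DRN 6, that of en2a in M_DRN was 2.55 CPM without M_DRN 15 and that of pax5 in M_DRN was 0.789 CPM without M_DRN 5.

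The GABA and glycine list was higher in R_DRN (camera adjusted p = 0.000284), with 2 of 8 members passing, the GABA-synthesizing enzyme gene gad1b (193 ± 237 CPM) and the GABA transporter gene slc6a1b (1564 ± 726; 4 higher and 0 lower adjusted over the list alone). Hox genes were lower (camera adjusted p = 1.91e-09): hoxb3a averaged 0.0452 ± 0.136 CPM against 1961 in IN_P. The AMPA receptor gene gria1a averaged 1.46 ± 2.97 CPM in R_DRN and 700.1 in PT. Cerebellar neuron markers were lower as well (camera adjusted p = 0.00131), with 1 of 6 members called, neurod1, which did not pass limma, and so were forebrain and pretectum genes (1.74e-06). Serotonin identity genes were higher and ribosomal proteins lower with the preset correlation alone (adjusted p = 0.0124 and 1.27e-11, and 0.0602 and 0.0602 with an estimated correlation). For R_DRN, edgeR called 676 genes (465 higher and 211 lower), limma 214, and 144 passed both in the same direction; DESeq2 called 219 higher and 498 lower. The 7 genes higher than in each other group by limma, chosen after the values were seen, included ncaldb (79.2 ± 98.9 CPM), ephb2a, chrna2a, en2a and pax5. The mean of gad1b in R_DRN was 121 CPM without R_DRN 6.

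M_DRN carried the highest mean of en1b, an engrailed gene, at 6119 ± 2915 CPM (SD, n = 10), with 5379 ± 1677 in R_DRN, 2825 ± 2822 in C_DRN and 253 ± 548 in IN_A. The serotonin genes slc6a4a (1788 ± 571), ddc (6739 ± 2721), the enzyme that makes serotonin from its precursor, and gch1, needed for the cofactor of tph2, were higher. Of 18 serotonin identity members tested, 7 were higher and 0 lower (8 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.0105 and an adjusted p of 0.0849 with an estimated correlation. The hepatocyte growth factor receptor gene met averaged 487 ± 247 CPM, rdh10a, a retinol dehydrogenase gene, 88.2 ± 99.2, and dkk2, a Wnt antagonist gene, 379 ± 349.7, with no other group over 9.78 for rdh10a. Hox genes (camera adjusted p = 5.68e-10), forebrain and pretectum genes (4.55e-08) and cerebellar markers (7.66e-05) were lower, the last with pcp4a at 5.32 ± 6.28 CPM against 2728 in MO. Mitochondrial transcripts had a camera adjusted p of 0.000359, also lower, and an adjusted p of 0.0849 with an estimated correlation. Ionotropic glutamate receptors, immediate early and stress genes, ribosomal proteins and muscle markers were lower in the same way (adjusted p = 0.0225, 0.0129, 2.25e-05 and 0.0495, and 0.201 to 0.337 with an estimated correlation). The mean of en1b in IN_A was 99 CPM without IN_A 36.

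The M_DRN libraries fell into 2 parts, chosen after the values were seen, 5 with 5942 to 7369 genes detected and 5 with 9254 to 9863 (M_DRN 14, 15, 17, 19 and 20). In CPM of the library total, serotonin identity genes summed to 18527 to 24106 in the first and 29488 to 32386 in the second. On that scale R_DRN and C_DRN averaged 19020 and 19630. TMM factors, by which scaled levels are divided, were 0.872 to 1.193 in the first part and at least 1.327 in the second. Divided by these factors, the sums of the 2 parts overlap, so they show no split on the TMM scale. The single genes that follow are in TMM-scaled CPM. The mean of ddc was 4546 CPM in the first part and 8931 in the second, while that of en1b was 8482 and 3755, that of slc6a4a 1979 and 1596 and that of gch1 1990 and 760, so the highest group means of en1b and ddc came from 1 part each. For M_DRN, edgeR called 574 genes (432 higher and 142 lower), limma 270, and 174 passed both in the same direction. The larger side turned with DESeq2 (213 higher and 425 lower). The peptide gene cart4 and the engrailed gene en2a, called higher in M_DRN by edgeR against the mean of the log levels of all 6 groups, did not pass limma (adjusted p = 0.218 and 0.666). In the test against each other group, chosen after the values were seen, 1 gene passed limma, the heme-binding protein gene hebp2 (67.4 ± 85.1 CPM). The mean of hebp2 in M_DRN was 44.8 CPM without M_DRN 5.

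C_DRN was marked by the peptide precursor gene cart4, of the family of cocaine- and amphetamine-regulated transcripts, at 20622 ± 6602 CPM (SD, n = 9) against 437 ± 1063 in M_DRN, 42.3 ± 119 in R_DRN and at most 7.34 in the rest (edgeR adjusted p = 6.56e-11, higher in all 9 libraries than the mean of any other group). The oxytocin receptor gene oxtr (202 ± 196), a dopamine receptor gene drd4-rs (134 ± 221, and 61.6 without its highest library, C_DRN 9), met (665 ± 389) and slc6a4a (1667 ± 1241) were also higher. Serotonin identity genes were higher than the mean of the log levels of the other groups (camera adjusted p = 0.000836). Of 18 members, 4 were called higher (fev, lmx1bb, slc6a4a and gch1) and 0 lower (5 higher and 0 lower adjusted over the list alone). In CPM of the library total, not the TMM scale of the test, the summed level of the list (19630 ± 4243) was below M_DRN (25790) and near R_DRN (19020). Of 8 serotonin receptor genes, 3 were higher (htr1ab, htr1b and htr1fa), without a call for the list (camera adjusted p = 0.126). Forebrain and pretectum genes (camera adjusted p = 1.36e-07) and cerebellar markers (0.00162) were lower, and the glutamate transporter gene slc17a6b had no count in any C_DRN library. Midbrain and isthmus genes were lower by camera alone (adjusted p = 0.0321, with 2 members called higher). Their summed level, 3658 ± 2622 in CPM of the library total, was below R_DRN and M_DRN but above the other groups (62.7 to 2396). The calls of lmx1bb, htr1b, htr1fa and slc17a6b did not pass limma. The mean of cart4 in M_DRN was 106 CPM without M_DRN 14, that of cart4 in R_DRN was 2.54 CPM without R_DRN 15 and that of cart4 in IN_A was 1.02 CPM without IN_A 49.

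The Hox list was lower in C_DRN by camera (adjusted p = 0.00012), while the median fitted change of its 6 members was positive (0.86) and 2 were called higher (hoxc4a and hoxc12b; 3 higher and 0 lower adjusted over the list alone). Counts of several genes rested on a single C_DRN library: hoxb3a (56.7 CPM), pyya (45.4 CPM) and hoxc4a were counted in C_DRN 12 alone, and adcyap1b averaged 131 CPM, or 4.82 without C_DRN 2. Neither hoxc4a nor hoxc12b passed limma. The edgeR call of pyya as higher in C_DRN had the opposite sign in limma (log2 change -1.21, adjusted p = 0.449). In all, 677 genes were called by edgeR (483 higher and 194 lower), 163 by limma and 109 by both in the same direction. By DESeq2, 238 were higher and 436 lower. Higher in C_DRN than in each other group by limma, a test chosen after the values were seen, were 4 genes: cart4, drd4-rs, tinagl1 (31.5 ± 32.9) and the relaxin-family receptor gene rxfp3.2b (308 ± 638). The mean of rxfp3.2b in C_DRN was 103 CPM without C_DRN 9.

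By edgeR and by limma, IN_A differed from the other groups at more genes than any other single group. It also had the most libraries (12) and the highest mean total count (3.36 M). Title numbers of 32 or more occurred only in IN_A, in all libraries but IN_A 7, and in IN_P. Whether these raised the number of genes was not tested. The calcium-binding protein gene calb2a (calretinin) averaged 6853 ± 2849.9 CPM (SD, n = 12) and at most 391 elsewhere, and the LIM-homeobox gene lmx1ba 1012 ± 619 CPM, counted in all 12 libraries. The homeobox gene nkx2.2a (376 ± 206), the axon guidance gene ntn1b, encoding a netrin (2641 ± 1494), and crabp1a, encoding a retinoic acid-binding protein (965 ± 704), were higher. For ntn1b and crabp1a IN_P was next, and for nkx2.2a its mean of 117 rested on IN_P 6. Of serotonin identity genes, 8 of 18 members rose above the mean of the log levels of the other groups and 2, gch1 and tph1b, lay below it (9 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.58e-07). In CPM of the library total, the summed level of the list, 17030 ± 3172, was not above that of IN_P (17030) or the DRN groups (19020 to 25790). It lay far above MO alone (2468). The test used TMM scaling, where a lower factor gives a higher scaled level. TMM factors were 0.583 to 0.945 in IN_A and higher in most M_DRN libraries. Divided by the factor of each library, the sums averaged highest in IN_A, with M_DRN next and ranges that overlapped. The call of tph1b did not pass limma. The GABA genes gad2 and slc32a1, which encodes the vesicular GABA transporter, were lower, and the GABA and glycine list had a camera adjusted p of 0.0135, and an adjusted p of 0.0805 with an estimated correlation. The mean of nkx2.2a in IN_P was 5.85 CPM without IN_P 6.

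Ribosomal protein genes were higher in IN_A, with 63 of 87 members called and 1 lower (69 higher and 2 lower adjusted over the list alone; camera adjusted p = 5.56e-37); their median log2 change was 1.41, where the median of all genes was 0.40. Markers of radial glia were higher too, at 5528 ± 2801 CPM summed against 869 to 1614 in the other groups, with 8 of 9 markers called (camera adjusted p = 5.61e-09), among them glula (2349 ± 1764), fabp7a (4165 ± 2005) and cx43 (114 ± 124). Proliferating progenitor markers (3 of 3, camera adjusted p = 0.00475) and oligodendrocyte markers (5 of 7, 0.000117) also rose. Cerebellar neuron markers (2 of 6, camera adjusted p = 0.00257) rose against the mean of the log levels of the other groups. Their summed level, 479.7 CPM, was below PT (849) and MO (3285). So did midbrain and isthmus (5 of 10; 0.00129) and Hox genes (5 of 6; 0.0123) against the mean of the log levels of the other groups. Neuropeptide precursors (0.00257) and ionotropic glutamate receptors (0.00249) were lower by camera, each with 2 or fewer members called higher and at most 3 called lower. With the preset correlation alone, serotonin receptors and immediate early and stress genes were lower and the mitochondrial genome higher (adjusted p = 0.0469, 0.0166 and 0.0182, and 0.0805, 0.2 and 0.186 with an estimated correlation). In all, edgeR called 1979 genes (1359 higher and 620 lower), limma 885, and 610 passed both in the same direction. The 25 genes higher than in each other group by limma, chosen after the values were seen, included calb2a, lmx1ba, nkx2.2a, the RNA-binding protein gene msi2a (4667 ± 1483) and bcam (626 ± 440.2).

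IN_P carried nkx6.1, a homeobox gene, at 633 ± 259.6 CPM (SD, n = 10), with IN_A next at 135 ± 233. The natriuretic peptide receptor gene npr1b (476 ± 311), the glycine receptor gene glra4a (187 ± 257), the secreted glycoprotein gene epd (1634 ± 2139) and slit3, encoding a repellent axon guidance protein (665 ± 454), were highest in this group. Hox genes were higher, with hoxb3a at 1961 ± 1192 and hoxd3a at 385 ± 386 CPM and 4 of 6 members called (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.46e-07). All 7 oligodendrocyte and Schwann cell markers tested were higher (camera adjusted p = 2.06e-11), the list averaging 3109 ± 5042 CPM against 1090.0 in IN_A and 23.8 to 437 elsewhere. The median of this list was 839.5 CPM in IN_P and 879 in IN_A, so the typical IN_P library was not above IN_A. The highest IN_P levels were in IN_P 9 (16095), IN_P 6 (6363) and IN_P 11 (4677). Muscle markers (5 of 7 called; camera adjusted p = 0.0131, and an adjusted p of 0.206 with an estimated correlation) and both microglia markers tested, apoeb and apoc1, were higher as well, the last 2 without passing limma. Proliferating progenitor markers rose as a list (camera adjusted p = 0.0086; 1 of 3 called). With the preset correlation alone so did ribosomal proteins and the mitochondrial genome (adjusted p = 2.44e-09 and 0.000962, and 0.123 and 0.113 with an estimated correlation). Serotonin receptors were lower (camera adjusted p = 0.00644) with 1 member called higher and 0 lower over all genes. The mean of nkx6.1 in IN_A was 81 CPM without IN_A 44, that of glra4a in IN_P was 113 CPM without IN_P 3 and that of the oligodendrocytes and Schwann cells list in IN_P was 1666 CPM without IN_P 9. The mean of the oligodendrocytes and Schwann cells list in R_DRN was 136 CPM without R_DRN 6.

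A single library weighed on several IN_P values. IN_P 6 held 1115 CPM of nkx2.2a where the other IN_P libraries had at most 35.9, 5631 CPM of ntn1b (at most 1275), 712 CPM of lmx1ba (at most 277.0), 16.4 CPM of nkx6.1 (at least 485), 107 CPM of hoxb3a (at least 1291) and no count of npr1b (at least 100.3). Without it, the IN_P means were 5.85 CPM for nkx2.2a, 385 for ntn1b and 34.3 for lmx1ba. The parvalbumin gene pvalb7 in IN_P rested on IN_P 42 (558 CPM, and a mean of 0.163 in the other 9). The edgeR calls of pvalb7 and lmx1ba as higher in IN_P did not pass limma (adjusted p = 0.586 for lmx1ba). Across IN_P, edgeR called 830 genes (656 higher and 174 lower), limma 262, and 192 passed both in the same direction. DESeq2 called 483 higher and 430 lower. By limma, 14 genes were higher in IN_P than in each other group, chosen after the values were seen, among them nkx6.1, npr1b, slit3, epd and nefma, a neurofilament gene (211 ± 248).

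MO held a set of genes that the other groups all but lacked. The peptide YY precursor gene pyya averaged 1546 ± 1245 CPM (SD, n = 11) and at most 5.05 elsewhere, and the transcription factor genes phox2bb (1110.1 ± 572), tlx3b (938 ± 484), tfap2a (242 ± 244) and tfap2b (204 ± 222) stayed at or below 25.7 in any other group. The homeobox gene shox2 reached 1694 ± 859 CPM, with 304 ± 223 in IN_P and 189.6 ± 195 in IN_A. All 6 Hox genes tested were higher (camera adjusted p = 5.47e-20), with hoxa4a (156 ± 193) at or below 5.47 elsewhere. Both tested vesicular glutamate transporter genes of the slc17a6 pair, slc17a6a (105 ± 88.1) and slc17a6b, were higher and slc17a8 was lower, and the glutamate list had a camera adjusted p of 0.03, and an adjusted p of 0.0578 with an estimated correlation. The mean of tlx3b in R_DRN was 0 CPM without R_DRN 5 and that of hoxa4a in IN_A was 0.601 CPM without IN_A 43.

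**Figure D4:**
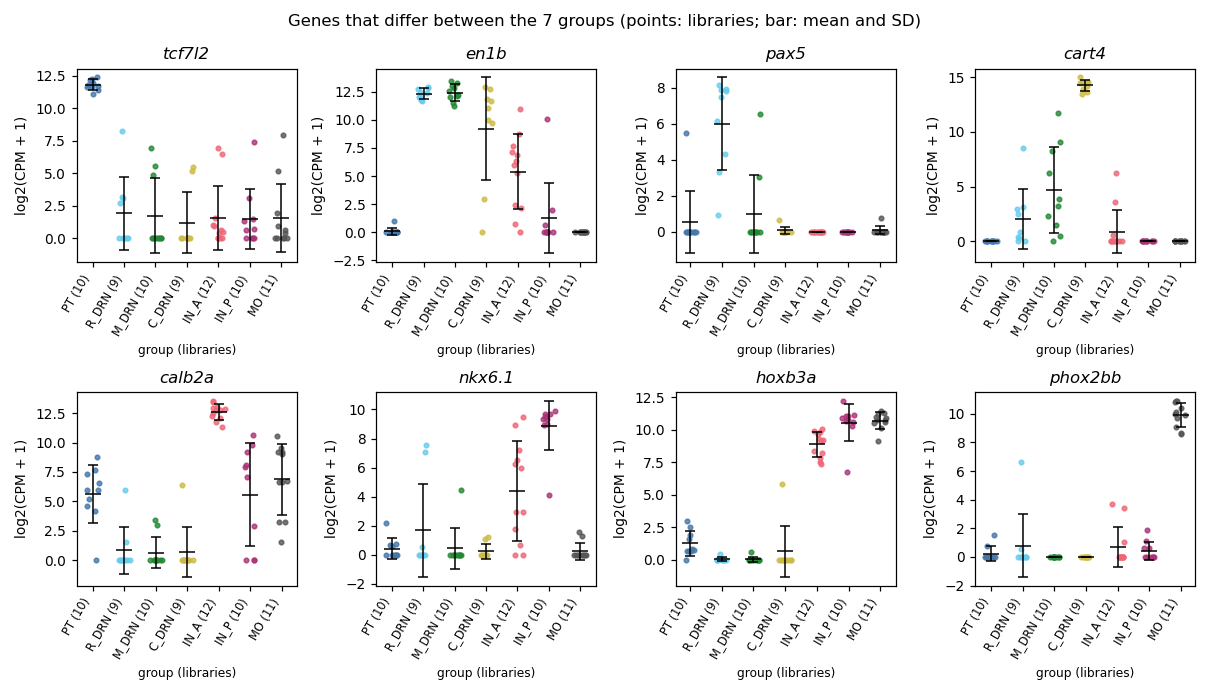
Levels of 8 genes that differ between the groups, as log2 of CPM plus 1 on the vertical axis and the 7 groups, with their number of libraries, on the horizontal axis. Points are libraries and bars are the mean and SD, and phox2bb averaged 1110.1 CPM in MO and at most 10.8 in any other group.

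The serotonin identity list was lower in MO, with 8 of 18 members lower and 4 higher (4 higher and 9 lower adjusted over the list alone; camera adjusted p = 3.43e-23). Lower were tph2 (log2 change -2.55), slc6a4a (-6.48), slc18a2 (-5.74), ddc (-3.10), fev (-9.16), gata2a, qdpra and gata3, a transcription factor gene that averaged 15.5 ± 33.4 CPM in MO and 729.6 to 1264 elsewhere. Higher than the mean of the log levels of the other groups were slc6a4b, tph1b, lmx1bb and lmx1ba, of which slc6a4b alone passed limma. The mean of lmx1ba was 1012 CPM in IN_A and at most 102 in any other group, MO included. The netrin gene ntn1b averaged 0.0734 ± 0.167 CPM in MO, and avpr1ab, a vasopressin receptor gene, and the calcium sensor gene ncs1a had no count in its 11 libraries. Ionotropic glutamate receptors (5 of 18 higher, 0 lower; camera adjusted p = 2.39e-07), immediate early and stress genes (7 of 21 higher; 1.8e-06) and cerebellar neuron markers (3 of 6 higher; 0.00337) rose as lists, the last with pcp4a at 2728 ± 1360.5 CPM. Potassium channel genes had a camera adjusted p of 0.0385 (5 of 35 higher, among them kcnd1), and an adjusted p of 0.15 with an estimated correlation. Other lists called with the preset correlation alone were GABA-A and glycine receptors, cadherins and contactins, ribosomal proteins and muscle markers, higher (adjusted p = 0.0204, 0.0434, 1.49e-05 and 0.00383), and the GABA and glycine list, radial glia and oligodendrocyte markers, lower (0.0395, 0.0204 and 0.00413). With an estimated correlation their adjusted p was 0.0991 to 0.274. Of all genes, edgeR called 1069 genes (736 higher and 333 lower), limma 501, and 337 passed both in the same direction. The sides were nearly even with DESeq2 (548 higher and 538 lower). The 42 genes higher than in each other group by limma, chosen after the values were seen, included pyya, phox2bb, tlx3b, slc6a4b, mab21l2 (926 ± 478), rbfox3a (1182 ± 422) and the neuronal activity gene egr4 (1528 ± 1089). The mean of gata3 in MO was 6.27 CPM without MO 3.

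The titles put 3 groups under the name DRN and 2 under IN, and the contrast of their means asked what sets the groups under the 2 names apart. The DRN groups carried met, zbtb16b, ucn3l and hmx3b: met had no count in the 22 IN libraries and averaged 226 to 665 CPM in the DRN groups, a difference of at least 9531-fold (from 3 counts over all 22 libraries, 0.0482 CPM), and zbtb16b, a zinc finger transcription factor gene, averaged 315 ± 221 in M_DRN and 7.76 ± 25.9 in IN_A. The IN groups carried hoxb3a (568 and 1961 CPM in IN_A and IN_P), shox2, crabp1a, calb2a and hoxb2a, with at most 10.2 CPM of any of the 5 in a DRN group. Of the Hox list, 4 of 6 members were lower in the DRN groups and 0 higher (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 1.57e-08). Serotonin receptors (5 of 8 higher in DRN, among them htr1aa, htr1ab and htr1d; camera adjusted p = 0.0103), the GABA and glycine list (0.00528) and neuropeptides (0.0247) were higher in the DRN groups, and htr1aa did not pass limma. The mean of met in R_DRN was 150.4 CPM without R_DRN 7, that of zbtb16b in IN_A was 0.273 CPM without IN_A 43 and that of crabp1a in C_DRN was 5.32 CPM without C_DRN 6.

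Ribosomal proteins (56 of 87 lower in DRN; camera adjusted p = 2.12e-25), the mitochondrial genome (6 of 13; 0.000448), cerebellar markers (4 of 6; 0.000252), oligodendrocyte markers (5 of 7; 2.81e-07), proliferating progenitor markers (2 of 3; 0.00528) and forebrain and pretectum genes (7 of 14, with 2 higher in DRN; 0.000106) were higher in the IN groups. Muscle markers were too (4 of 7; camera adjusted p = 0.0383, and an adjusted p of 0.313 with an estimated correlation). Among serotonin genes, slc6a4a and tph2 were higher in the DRN groups (adjusted p = 0.00715 and 0.0283 by edgeR), while fev (0.661) and ddc (0.323) showed no detectable difference. In all, edgeR called 1905 genes (831 higher and 1074 lower in DRN), limma 1673 (929 higher and 744 lower), and 1056 passed both in the same direction, so the larger side differed between the tests. With DESeq2 size factors the share called higher in DRN moved from 43.6% to 32.2%.

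Within the DRN, R_DRN and M_DRN differed at 36 genes by edgeR (18 higher and 18 lower in R_DRN) and at 18 by limma. DESeq2 called 112 higher and 189 lower. Called by edgeR and limma were 2 genes, ncaldb, which encodes a neuronal calcium sensor (79.2 ± 98.9 CPM in R_DRN and 0.126 ± 0.271 in M_DRN), and hspb1, a small heat shock protein gene (98.1 ± 137 and 0.0492 ± 0.156). Midbrain and isthmus genes were higher in R_DRN by camera (adjusted p = 4.79e-05) with 0 of 10 members called higher and 1 lower (1 higher and 1 lower adjusted over the list alone). In CPM of the library total, not the TMM scale of the test, their summed level was not higher (7942 ± 1938 in R_DRN and 8098 ± 2560 in M_DRN). The adrenergic, dopamine, acetylcholine and orexin receptors were higher in R_DRN as a list (camera adjusted p = 0.000229) with 0 called. Immediate early and stress genes were higher with the preset correlation alone (adjusted p = 0.0478, and 0.569 with an estimated correlation). The glutamate receptor gene gria3a, with counts in 3 R_DRN libraries, and the semaphorin gene sema3fa, with counts in 5 M_DRN libraries, were called by edgeR and not by limma (adjusted p = 0.668 and 0.591). Fitted to these groups alone, edgeR called 0 genes, with 169 of 5409 tested at an unadjusted p under 0.05. The mean of hspb1 in R_DRN was 57.3 CPM without R_DRN 9.

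R_DRN and C_DRN differed more. The genes en2b, en2a, pax5 and chrna2a and the zinc finger gene zeb2b (229 ± 285 CPM against 0.0616 ± 0.185) were higher in R_DRN, and cbln2b, a cerebellin gene (0.0995 ± 0.197 against 257 ± 263), nxph2b, a neurexophilin gene (0 against 199 ± 342), tinagl1 and cart4 in C_DRN. Of 10 midbrain and isthmus members, 3 were higher in R_DRN and 2 lower (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.59e-07). The GABA and glycine list, with 0 members called over all genes and 2 higher and 0 lower adjusted over the list alone, had a camera adjusted p of 0.006, and an adjusted p of 0.0934 with an estimated correlation. Adrenergic, dopamine, acetylcholine and orexin receptors were higher and ribosomal proteins lower in R_DRN with the preset correlation alone (adjusted p = 0.006 and 0.000455, and 0.0587 and 0.501 with an estimated correlation). The calls of hoxb3a, pyya and adcyap1b as lower in R_DRN did not pass limma (adjusted p = 0.96, 0.946 and 0.842) and rested on C_DRN 12 and C_DRN 2, without which the means were 0, 0 and 4.82 CPM. Together, edgeR called 187 genes (92 higher and 95 lower in R_DRN), limma 40, and 15 passed both; fitted to these groups alone, edgeR called 1. The mean of zeb2b in R_DRN was 150.4 CPM without R_DRN 6 and that of nxph2b in C_DRN was 92.7 CPM without C_DRN 9.

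M_DRN and C_DRN differed at 7 genes by edgeR (1 higher and 6 lower in M_DRN) and at 16 by limma, with 3 shared. With DESeq2 the direction turned, with 196 higher and 129 lower. Called by edgeR and limma and named by the rule were en2b (208 ± 349 CPM in M_DRN and 0.539 ± 1.08 in C_DRN) and nxph2b, which had no count in M_DRN and was at least 1370.4-fold higher in C_DRN, a bound that uses the C_DRN mean of 199 ± 342 and falls without C_DRN 9. The calls of hoxb3a and pyya rested on C_DRN 12 and did not pass limma (adjusted p = 0.97 and 0.957). The gene cart4 averaged 437 CPM in M_DRN and 20622 in C_DRN. One list was called, immediate early and stress genes, lower in M_DRN (camera adjusted p = 0.000647, and an adjusted p of 0.254 with an estimated correlation), with 0 members called over all genes. Of 100 groupings of these libraries, 26 gave as many edgeR calls, and fitted to these groups alone edgeR called 0 genes, with 171 of 5192 tested at an unadjusted p under 0.05. The mean of en2b in M_DRN was 101 CPM without M_DRN 6, that of nxph2b in C_DRN was 92.7 CPM without C_DRN 9 and that of cart4 in M_DRN was 106 CPM without M_DRN 14.

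IN_A and IN_P differed at 688 genes by edgeR (222 higher and 466 lower in IN_A) and 188 by limma, with 78 shared. With DESeq2, 497 were higher and 470 lower. Lower in IN_A were islr2, a leucine-rich repeat gene of developing axons (0.919 ± 1.37 CPM against 1655 ± 1326 in IN_P), npr1b, the ephrin receptor gene epha4b (1.46 ± 1.75 against 521 ± 356), the kainate receptor gene grik4 (0.0266 ± 0.092 against 101 ± 99.3), nxph2b and gad2. Radial glia markers were higher in IN_A as a list (camera adjusted p = 1.42e-09). Of 9 members, 2 were called, glula and, by edgeR alone, mfge8a (4 higher and 0 lower adjusted over the list alone). Serotonin identity genes (camera adjusted p = 0.00391, 1 higher and 2 lower of 18) and cerebellar markers (0.0087, no member called) were higher too. In CPM of the library total, not the TMM scale of the test, serotonin identity genes summed to 17030 in IN_A and 17030 in IN_P. Divided by the TMM factor of each library, the sums averaged higher in IN_A, with ranges that overlapped. Ribosomal proteins had a camera adjusted p of 1.42e-09 (0 higher and 1 lower of 87), and an adjusted p of 0.161 with an estimated correlation. Midbrain and isthmus genes, higher, and ionotropic glutamate receptors, lower, passed with the preset correlation alone (adjusted p = 0.0393 for both, and 0.0667 and 0.193 with an estimated correlation). The genes of largest fitted increase in IN_A rested on few libraries: synm averaged 293 CPM, or 55.7 without IN_A 56, cdh13 138, or 15.4 without IN_A 36, and neither passed limma (adjusted p = 0.0741 and 0.262). Fitted to these groups alone, edgeR called 17 genes.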

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

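In this part the tests of depth of IN_A 7 and IN_P 6, and the test that IN_P 6 alone holds IN_A cells together with the rule that decides it, were chosen only after the result was seen. A library was looked at again when it lay far from the 8 or 9 others of its group, by a gap that chance alone gives in about 1 in 20 groups of values. IN_A (12 libraries) and MO (11) were too large for this rule and were not screened. Of 216 groups of values, 36 held such a library, where 10.8 were expected by chance.

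M_DRN 13 and R_DRN 9 had 4 such values each and M_DRN 5 had 3. M_DRN 13 had a mitochondrial share of 2.76% (others 0.883 to 1.88), slc17a6b at 16.7 CPM (others 0), gad2 at 39.9 (594 to 1735) and a GABA and glycine list level of 1190 (2841 to 5244). R_DRN 9 had ddc at 713 (2418 to 5867), sodium, calcium and HCN channels at 1444 (3389 to 4402), axon guidance at 1750 (3551 to 4702) and cerebellar markers at 3.76 (79.5 to 437). M_DRN 5 had gad1b at 4.03 (36.2 to 346), sodium, calcium and HCN channels at 1350 (2934 to 5501) and oligodendrocyte markers at 0 (28.8 to 825).

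PT 23 had 3.89 M counts (others 1.14 to 1.86). R_DRN 6 had tph2 at 2184 CPM (3324 to 4395), R_DRN 11 had slc17a8 at 328 (0 to 7.35), and M_DRN 20 had slc32a1 at 1.97 (58.5 to 391). C_DRN 2 had tph1a at 42.8 and IN_P 2 at 3.15, where the others had 0. For genes of other amines and acetylcholine R_DRN 12 had 12.6 (0 to 1.79) and IN_P 41 had 86.5 (0 to 8.28). Hox genes were at 35.1 in R_DRN 15 (0 to 1.79), 405 in M_DRN 6 (0 to 9.68) and 492 in IN_P 6 (1561 to 4630). IN_P 9 had GABA-A and glycine receptors at 345 (1119 to 1914), C_DRN 11 cadherins and contactins at 2992 (5032 to 7855), C_DRN 12 ribosomal proteins at 79610 (25522 to 39310) and C_DRN 13 mitochondrial transcripts at 8054 (14740 to 23617). Radial glia markers were at 3863 in M_DRN 10 (596 to 1594) and 219.9 in IN_P 3 (874 to 2870.3). Red blood cell markers were at 109 in PT 5 (0 to 5.48) and 300 in IN_P 2 (0 to 14.6), and skin markers at 46.5 in R_DRN 12 (0 to 3.33). Photoreceptor markers were at 295 in PT 20 (0 to 5.55), 179 in R_DRN 8 (0 to 4.24), 19.4 in M_DRN 17 (0 to 2.02), 82.1 in C_DRN 2 (others 0) and 0.712 in IN_P 12 (others 0).

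IN_A 7 and IN_P 6 were each nearest to a library of the other IN group. On a scale from the other IN_P libraries (0) to the other IN_A libraries (1), IN_A 7 lay at 0.981, among the IN_A libraries (0.791 to 1.07), and IN_P 6 at 0.731, above the IN_P libraries (-0.0388 to 0.196), which argues against swapped labels and against cells of both groups in both pools. Low depth of IN_P 6 is argued against, since 30% of its group had a lower total, while low depth of IN_A 7 cannot be told apart, since only 8.33% of its group had a lower total and 8.33% fewer genes. A hypothesis that remains is that IN_P 6 alone may hold IN_A cells (0.731), by a mixed pool or a wrong label, which were not separated. Its position below all IN_A libraries and calb2a at 1639 CPM (other IN_P at most 875, IN_A at least 2516) go with a mixed pool, while no count of npr1b (other IN_P at least 100.3) and nkx2.2a at 1115 CPM (IN_A at most 900.5) go with a wrong label. A biological difference between pools of IN_P stays untested.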

How the results depend on the processing

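The tests with limma, the test of each group against each other group and the fit without IN_A 7 and IN_P 6 were chosen only after results were seen. Calls by edgeR depended on the setting, and the cause was not tested. Without a filter on low counts, over 20635 genes, the counts were 10997 for any difference, 2875 for PT, 2843 for R_DRN, 3039 for M_DRN, 2834 for C_DRN, 4395 for IN_A, 3487 for IN_P, 3660 for MO, 3753 for DRN against IN, 2034 for R_DRN against M_DRN, 2143 for R_DRN against C_DRN, 1895 for M_DRN against C_DRN and 3455 for IN_A against IN_P. With limma they were 358 for PT, 214 for R_DRN, 270 for M_DRN, 163 for C_DRN, 885 for IN_A, 262 for IN_P, 501 for MO, 18 for R_DRN against M_DRN, 40 for R_DRN against C_DRN, 16 for M_DRN against C_DRN (7 by edgeR) and 188 for IN_A against IN_P. With DESeq2 they were 301, 465 and 325 for R_DRN against M_DRN, R_DRN against C_DRN and M_DRN against C_DRN, and with genes detected as a covariate 68 for R_DRN against M_DRN and 47 for M_DRN against C_DRN. Fitted to only the compared groups, edgeR called 0 genes for R_DRN against M_DRN (169 at an unadjusted p under 0.05), 1 for R_DRN against C_DRN, 0 for M_DRN against C_DRN (171 unadjusted) and 17 for IN_A against IN_P. The replicate block (50 libraries share a number, and none of 75 pairs that share one correlated over 0.1) left 30 residual degrees of freedom and 655 genes for any difference, 37 for PT, 58 for R_DRN, 27 for M_DRN, 24 for C_DRN, 5 for IN_P, 64 for MO, 19 for DRN against IN, 1 for R_DRN against M_DRN and 10 for R_DRN against C_DRN, and by edgeR 0 for IN_A (518 unadjusted), 0 for M_DRN against C_DRN (660) and 0 for IN_A against IN_P (485), where limma without the block called 885, 16 and 188. With an estimated correlation 56 of 92 list calls passed. In limma the change of pyya in C_DRN was -1.21 and that of slc17a8 in IN_A -1.89, opposite to edgeR. Of 333 values of named genes, 317 were the same with DESeq2, 324 with its size factors and 269 with limma. With the replicate block, which held IN_A 7 as the only IN_A library, 147 were the same. Without IN_A 7 and IN_P 6 all 20 main results, which are counts of genes, stayed of similar size but were not equal. R_DRN against M_DRN fell from 36 to 25 genes and R_DRN against C_DRN from 187 to 172. For IN_A against IN_P, 138 edgeR calls met the conditions on detection and medians, and 109 of them stayed. DESeq2 size factors moved the median log2 change of all genes from 0.40 to 0.71 in IN_A, from -0.10 to -0.42 in DRN against IN, from 0.20 to 0.41 in IN_A against IN_P, from 0.11 to -0.15 in M_DRN, from 0.11 to -0.08 in R_DRN, from -0.03 to -0.20 in M_DRN against C_DRN and from 0.01 to -0.11 in R_DRN against C_DRN. With DESeq2 the share of calls that were higher moved from 67.7% to 38.3% in PT, 68.8% to 30.5% in R_DRN, 75.3% to 33.4% in M_DRN, 71.3% to 35.3% in C_DRN, 79.0% to 52.9% in IN_P, 68.8% to 50.5% in MO, 50% to 37.2% in R_DRN against M_DRN, 14.3% to 60.3% in M_DRN against C_DRN and 32.3% to 51.4% in IN_A against IN_P, and by under 10 points elsewhere. The alternative depth rule left out no library and gave no values.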

Other observations

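In this part the tests of dilution, yield and paralogs in MO and the counts of genes higher than in each other group were chosen only after the result was seen. The parting of the M_DRN libraries was chosen then too. The M_DRN libraries fell into 2 parts by the number of genes detected after thinning, 5164 to 6811 in M_DRN 5, 6, 10, 12 and 13 and 8775 to 9660 in M_DRN 14, 15, 17, 19 and 20. Mean total counts were 2.34 M in the first part and 1.80 M in the second. The 2 parts follow the numbers in the titles, from 5 to 13 in the first and from 14 to 20 in the second. In PT, IN_A and MO many nearest libraries also carried neighbouring numbers. Pairs nearest to each other included PT 3 and 4, PT 14 and 15, MO 1 and 2, MO 5 and 6, IN_A 32 and 33, IN_A 35 and 36, and IN_A 55 and 56. Other such pairs did not, such as IN_P 9 and 40. The labels give no batch and do not say whether the numbers follow the order of collection. No explanation of the parts was tested.

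MO pools held tph2 but almost no slc6a4a and slc18a2. In MO, tph2 kept 11.5% of its PT level (bootstrap interval 6.74 to 18.9), slc6a4a 1.19% and slc18a2 1.64%, so that tph2 kept 9.70 times (4.26 to 789) the share of slc6a4a and 7.02 times (1.97 to 725) that of slc18a2, which argues against dilution with cells that make no serotonin as the whole cause. The shares of both transporter genes rested in part on MO 8 (56.8 CPM of slc6a4a and 67.5 of slc18a2), and would be lower without it. Dilution in part stays open, since ddc kept 9.68% (4.77 to 16.7), and tph2 1.19 times (0.723 to 2.18) the share of ddc. Thinned MO libraries detected 6713 genes, fewer than 5 groups (6825 to 7677), but IN_A, with 6058, counted slc6a4a in all 12 libraries, which argues against a lower yield. Reads of slc6a4a counted under slc6a4b are argued against by at most 0.0233% of the sum of both genes under slc6a4b in another group, and would not explain slc18a2. The sum itself decides nothing, since it kept 14.1% of its PT level (115 and 819 CPM), near the share of tph2, and the highest MO library reached 300.6 CPM, above the lowest PT library (279.8). A different way of handling serotonin in MO neurons may remain as a hypothesis, which was not tested apart from these.

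Radial glia markers were higher in IN_A. Over the 12 IN_A libraries 9 markers had a median pairwise correlation of 0.209, where 1000 random lists of the same size had a median of 0.0119 and 0.4% reached as much, so RNA of radial glia carried into the pools may explain them. With genes detected as a covariate 8 of 8 markers kept their call. This cannot decide whether fewer genes detected were the cause, since the covariate was the unthinned number, which hardly differed (permutation p = 0.414). Its mean was 7111 in IN_A and 7249 to 8160 elsewhere. After thinning IN_A had the fewest genes (6058, and 6713 to 7677 elsewhere), and that number was not used as a covariate. The most abundant markers were fabp7a (4165 CPM) and glula (2349). Pools were picked for GFP by pipette, and RNA carried over from neighbouring cells was not measured. Expression of these genes by IN_A neurons stays open and untested.

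Random regrouping of the libraries (100 groupings, the real one included) argued against chance for most counts. The shares were not corrected for the 45 counts compared. Pools from the same fish, which the labels do not give, were not kept together, nor were libraries with neighbouring title numbers. With 1 of 100 groupings as large, the real count of genes by edgeR and the highest other were 2521 and 848 for any difference, 745 and 504 for PT, 676 and 506 for R_DRN, 574 and 481 for M_DRN, 677 and 543 for C_DRN, 1979 and 625 for IN_A, 830 and 464 for IN_P, 1069 and 462 for MO, 1905 and 345 for DRN against IN, 36 and 18 for R_DRN against M_DRN, 187 and 21 for R_DRN against C_DRN and 688 and 519 for IN_A against IN_P. By limma they were 1848 and 6, 358 and 21, 214 and 10, 270 and 12, 163 and 5, 885 and 17, 262 and 4, 501 and 4, 1673 and 6, 18 and 4, 40 and 22 and 188 and 75 in the same order, and 16 and 9 for M_DRN against C_DRN. For edgeR and M_DRN against C_DRN chance could not be excluded (7 and 279, 26 of 100 as large), and groupings with several times the real count point to a structure of the samples or to false calls by edgeR, neither of which was tested on them. Genes higher than in each other group numbered 36 in PT (highest other 1), 7 in R_DRN, 1 in M_DRN, 4 in C_DRN, 25 in IN_A, 14 in IN_P and 42 in MO (highest other 0 for these 6).

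For lists called by camera, no regrouping called as many for PT (10 lists, highest other 8), M_DRN (9 and 6) and IN_A (14 and 7). The same held for MO (14 and 6), DRN against IN (11 and 9) and IN_A against IN_P (6 and 5), the last 2 by narrow margins. This argues against chance only before a correction for the number of counts compared. Few groupings were as large for R_DRN (8 and 10, 2 of 100), IN_P (7 and 7, 3 of 100) and R_DRN against C_DRN (4 and 4, 2 of 100). Without a correction for the number of counts compared, these shares do not exclude chance. Nor could chance be excluded for C_DRN (5 and 7, 9 of 100), R_DRN against M_DRN (3 and 4, 6 of 100) and M_DRN against C_DRN (1 and 4, 60 of 100).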
